A study of Mus musculus with 4 samples.

How the data were processed

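Liver RNA of female mice was measured on 4 Affymetrix MG_U74Av2 oligonucleotide arrays. The labels place 1 array in each of 4 groups made by genotype (wild type or HSL-null, which lacks the hormone-sensitive lipase encoded by Lipe) and diet (ND with 11% or FD with 58% of energy from fat, for 6 months). Each array carried RNA from 1 pool, of 6 livers in 3 groups and of 4 livers in the HSL-null FD group. Per the labels' protocols, RNA was purified on columns after a phenol-based extraction and labelled with biotin. The table deposited by the authors holds 1 intensity per probe set and array on a linear scale, and the submitters' processing notes name MAS5, the Affymetrix summary algorithm, with a version not given in the sources used here. The 2% trimmed mean was between 100.085 and 100.094 on the 4 arrays, so the deposited values had been scaled to a common mean. Detection calls were not used here. Other files deposited by the authors hold run settings in words and numbers, with no expression value. They gave 1 chip lot, 1 scan day and 2 solution lots, and each genotype had its own solution lot, so lot and genotype cannot be told apart. The settings named the same diet as the label on 4 of 4 arrays.

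The table has 12488 probe sets, of which 66 are controls. In the platform annotation used, 10833 of the 12422 other probe sets had 1 gene, 396 had several and 1193 had none, and the probe sets with several or none were not named. Gene identifiers were matched to a RefSeq gene table of the assembly GRCm38.p6, which held the genes of 10817 of the 10833 probe sets, and 0 symbols needed a change. The table served for names and for which genes neighbour each other, and its coordinates are not given.

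Signals under a floor of 6.1, the 25th percentile of all values of non-control probe sets, were raised to it and taken to log2. Probe sets were kept where the mean of the 4 arrays was at least 26.9, the median of those means. That left 5615 probe sets and 4829 genes, each represented by its brightest probe set. Genes counted as different at a 2-fold ratio, which is a log2 ratio of 1 in size. A gene on the floor on 1 array of a ratio is given as at least N-fold different, with the floor as the lower signal. As 1 array stood for each group, there was no test and no p-value, and the number of arrays limits the precision. The 1 estimate of measurement error came from 687 genes with a second kept probe set. The difference between the log2 ratios of their 2 brightest probe sets, divided by the square root of 2, had an SD of 0.298. This is the root mean square of the SDs of the 4 comparisons. On average 2.98% of the pairs lay 2-fold or more apart. The SD covers error that differs between the probe sets of a gene. Labelling and hybridisation error that the probe sets share on an array cancels in it. No array was repeated, so that shared error was not measured, and neither was variation between animals.

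The comparisons were genotype on each diet, diet in each genotype, genes 2-fold different in the same direction in both, and the difference between the 2 genotype ratios. The 2 genotype ratios share no array, and neither do the 2 diet ratios. Where a mean is given with an SD and n = 2 array pairs, the pairs are the 2 diets or the 2 genotypes and not replicates. Such an SD is the difference between the 2 ratios divided by the square root of 2. It includes any true difference between diets or genotypes and does not measure the precision of repeats. The number of genes shared by 2 comparisons was set beside the number for independent lists and beside the mean of 1000 draws of genes matched on expression. The 28 gene lists cover lipid, glucose, amino acid, xenobiotic and retinoid metabolism, sex-biased liver genes, the clock, stress and inflammatory responses, the cell cycle, oxidative phosphorylation and markers of cell types. Each list was described by the median log2 ratio of its measured members and that median's percentile among 10000 random lists of the same size matched on mean signal in 20 bins. A list lay outside the range where the median was under the 2.5th or over the 97.5th percentile. This describes these arrays and is no test of the conditions. The gene lists, the rule for named genes, the comparisons and 11 of the alternatives for the counts were fixed before the data were examined.

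The rule for named genes took Lipe on every array, the 10 higher and 10 lower genes with the largest smaller ratio of the 2 for genotype in both diets and for diet in both genotypes, and the 5 highest and 5 lowest genes of each single comparison and of the difference in genotype ratio. These genes were to be above the floor on every array of the comparison. From each list it took up to 4 members with the largest ratios plus the gene on which a list centres. Genes named outside this rule are said to have been chosen after their values were seen.

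The alternatives were quantile normalization, median scaling and cyclic loess between arrays, a floor at the median, a pseudocount equal to the floor in place of a floor, no filter on low values, a stricter filter at the 75th percentile of the mean signals, the mean of a gene's probe sets, leaving out probe sets whose suffix marks shared or incomplete probe selection, and thresholds of 1.5-fold and 3-fold. An alternative without the 83 kept marker genes of cell types other than hepatocytes was added after seeing the data. The criterion by which a list counted as altered under an alternative, leaving or entering the range of random lists or changing sign, was also settled after the values under the alternatives had been seen, as was the limit of 0.1 for a correlation.

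The code was tested on simulated data for HSL-null against wild type on FD, with 4828 genes and the error of 0.298. At the 2-fold threshold it recovered 8% of 50 genes with a true 1.5-fold change, 39.6% of 48 genes with a true 2-fold change, 98% of 49 genes with a true 3-fold change and 100% of 49 genes with a true 4-fold change. It called 2 unchanged genes, and 4% of 200 lists without change lay outside the range. The simulated error was independent between genes and of 1 size at every signal, without error shared on an array. These figures therefore test the code and do not estimate how many of the real calls are false. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for cyclic loess.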

Results

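Liver gene expression was compared between wild-type and HSL-null female mice, killed at the age of 8 months in the fed state, on a normal diet (ND) or a high-fat diet (FD). Hormone-sensitive lipase, encoded by Lipe, hydrolyses stored acylglycerols and cholesteryl esters. The study asked how its general loss affects metabolism of the liver. The 4 groups were wild type on ND, wild type on FD and HSL-null on ND, with 6 livers in each pool, and HSL-null on FD, with 4 livers in the pool. Each pool was hybridised to 1 array, so there were no replicates, no difference was tested, and "higher" and "lower" describe these 4 pools. The median signal of the non-control probe sets was 27.8 in wild type on ND, 25.2 in wild type on FD, 25.4 in HSL-null on ND and 28.3 in HSL-null on FD, and 24.1 to 26.0% of the probe sets per array lay at or under the floor of 6.1. Over the 4829 genes kept, the SD of the log2 ratio between 2 arrays was smallest for FD against ND in HSL-null liver, at 0.32, and largest for HSL-null against wild type on FD, at 0.45. The SD of a log2 ratio from disagreement between probe sets of a gene, which leaves out error shared on an array, was 0.298. Some control signals were lower on both FD arrays, as the 18S probe sets had means of 192.2 on ND and 84.2 on FD in wild type and of 307.1 and 99.1 in HSL-null liver, and the hybridisation spikes had geometric means of 482.0 and 308.4 and of 409.5 and 328.1. The poly-A spikes went opposite ways, with geometric means of 1412 on ND and 2179 on FD in wild type and of 1781 and 1510 in HSL-null liver. Whether these control signals touched the comparisons was not tested.

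Lipe was lower in both HSL-null pools. Its signal was 28.0 in wild type on ND and 34.0 in wild type on FD, against 11.9 in HSL-null on ND and 15.9 in HSL-null on FD. The mean log2 ratio of HSL-null to wild type was -1.17 ± 0.10 (SD, n = 2 array pairs, 1 per diet, which are not replicates). The mean signal of Lipe, 22.45, lay under the filter of 26.9, so Lipe is not among the 4829 genes. Where its probes lie relative to the deleted part of the gene is not given in the sources used here, so these values check the labels only in part.

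The genes that differed between genotypes on both diets were few, and 2 members of the cytochrome P450 2b family, Cyp2b9 and Cyp2b13, differed most. Both encode steroid and drug hydroxylases of female-type liver. Cyp2b9 had signals of 1046 on ND and 1632 on FD in wild type, and of 165.7 and 2.1 in HSL-null liver, which made it 6.31-fold lower on ND and at least 268-fold lower on FD. Cyp2b13 had signals of 129.1 and 610.0 in wild type and of 3.2 and 1.3 in HSL-null liver, at least 21.2-fold lower on ND and at least 100-fold lower on FD. Igfbp1, a hepatic insulin-like growth factor binding protein that insulin represses, was higher in both HSL-null pools, by 3.93-fold on ND and 6.4-fold on FD, with a mean log2 ratio of 2.33 ± 0.50 (SD, n = 2 array pairs). Its signals were 419.7 and 270.8 in wild type and 1648 and 1734 in HSL-null liver, read by a probe set whose suffix marks probes shared within a gene family.

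Usp2 and Dbp, outputs of the circadian clock, were lower in both HSL-null pools, with mean log2 ratios of -2.32 ± 0.82 and -1.42 ± 0.52 (SD, n = 2 array pairs). Usp2 had signals of 104.1 and 189.1 in wild type and of 31.1 and 25.4 in HSL-null liver, and its other probe set gave log2 ratios of -1.02 on ND and -2.59 on FD. The clock list as a whole lay inside the range of random lists, with a median of -0.097 over 14 genes on ND (percentile 28.6) and 0.15 on FD (percentile 60.3), but without suffix probe sets it lay below the range on ND, at -0.29 (percentile 0.98). The list holds 2 arms of genes, described below, which can cancel in its median where their ratios are opposite. A median inside the range therefore does not show an unchanged clock. The output arm had medians of -0.63 on ND and -0.17 on FD, and the Arntl side 0.49 and 0.71. These medians include the genes whose ratios drew attention to the arms. Without those genes, the output arm had -0.041 and 0.069 over 5 genes, and the Arntl side 0.16 and 0.56 over 2. The difference between the arms then lay inside the range of random lists on both diets. Per1, a repressor within the clock, had log2 ratios of -0.95 and -1.89. On FD its signals were 27.0 and 7.3, and the ratio shrank to -0.016 with the floor at the median. The heat shock genes Hspa1b (log2 ratios -1.63 and -2.21) and Hsph1 (-0.81 and -0.86), which encode chaperones, were lower too. Tbc1d10a, a GTPase activator, had -2.68 and -1.22 at its brightest probe set, but -0.17 and -0.40 at another. The sialyltransferase gene St8sia5 had mean -1.07, Llgl2 -0.83, Lamc1, which encodes a laminin chain, -0.76, and the cyclin gene Ccnt1 -0.73. With the floor at the median, St8sia5 had -0.64 on ND and -0.30 on FD, and Ccnt1 -0.36 on FD. Among higher genes, Gpcpd1, which encodes a glycerophosphocholine phosphodiesterase, had log2 ratios of 2.04 and 1.16, and the transcription factor gene Klf2 had 1.03 and 1.15, or 0.71 and 0.78 with the floor at the median. Cyb561, Tm9sf3, Pea15a, Cldn1, which encodes a tight junction protein, Ppp1r3c, which encodes a glycogen-targeting phosphatase subunit, Ddit4, an inhibitor of mTORC1 signalling, and Fbxo8 had mean log2 ratios from 1.16 for Cyb561 to 0.83 for Fbxo8. A second probe set of Cyb561 went the other way, with -0.47 and -0.25, and another of Tm9sf3 had 0.16 and 0.51.

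In all, 9 genes differed 2-fold or more in the same direction on both diets. The 3 higher genes were Gpcpd1, Igfbp1 and Klf2, where independent lists would share 0.447 and draws matched on expression 0.676, with at most 6. The 6 lower genes were Cyp2b13, Cyp2b9, Dbp, Hspa1b, Tbc1d10a and Usp2, where independent lists would share 0.495 and matched draws 0.64, with at most 5. A further 8 genes, named here after their values were seen, were lower in HSL-null liver on ND and higher on FD: Chrne, Cxcl1, Cytip, Igh-VS107, Il1b, Itgb2, Krtap3-1 and Ptpn22, against 0.969 for independent lists and 2.0 for matched draws, with at most 7. Across the 4829 genes, which are not independent replicates, the 2 genotype ratios had a Pearson correlation of 0.032 and a Spearman correlation of -0.070.

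**Figure D1:**
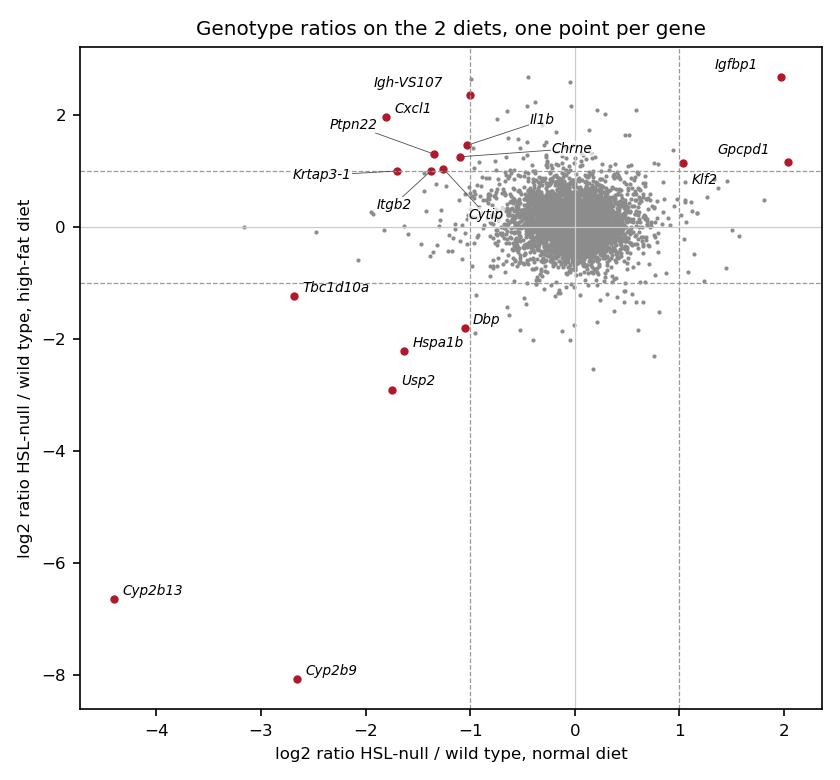
Log2 ratio of HSL-null to wild type on ND (horizontal axis) and FD (vertical axis), 1 grey point per kept gene, with values under the floor raised to it. Dashed lines mark a 2-fold ratio, and red points are the 9 genes past it in the same direction on both diets and the 8 lower on ND and higher on FD; Cyp2b9 and Cyp2b13 lie far below the others.

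Cyp2b9, Cyp2b13 and Cyp2b10 lie next to each other on the chromosome of Lipe, within 1 Mb of it. Of the 9 genes 2-fold different in the same direction on both diets, 2 genes, or 22.2%, lay within 10 Mb of Lipe, against 96 of the 4829 kept genes, or 1.99%. The 2 genes are Cyp2b9 and Cyp2b13, neighbours within 1 gene cluster. Cyp2b10, a cytochrome P450 induced by drugs and chosen here after its values were seen, had log2 ratios of -0.65 on ND and -1.43 on FD. Among the other 15 kept genes within 1 Mb, Ceacam1, which encodes a cell adhesion receptor, had 0.026 and 0.029, Gsk3a 0.21 and -0.088, and Bckdha 0.19 and -0.072, while Grik5 had 0.69 and 0.51, Ethe1 0.27 and 0.48, Erf -0.038 and -0.74, Rps19 0.15 and -0.67 and Arhgef1 -0.65 and 0.30. Xrcc1, a DNA repair gene, had -0.26 and 1.18, with a signal of 13.2 in wild type on FD, and 0.11 and -0.84 at a probe set under the filter. These genes were also chosen after their values were seen.

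**Figure D2:**
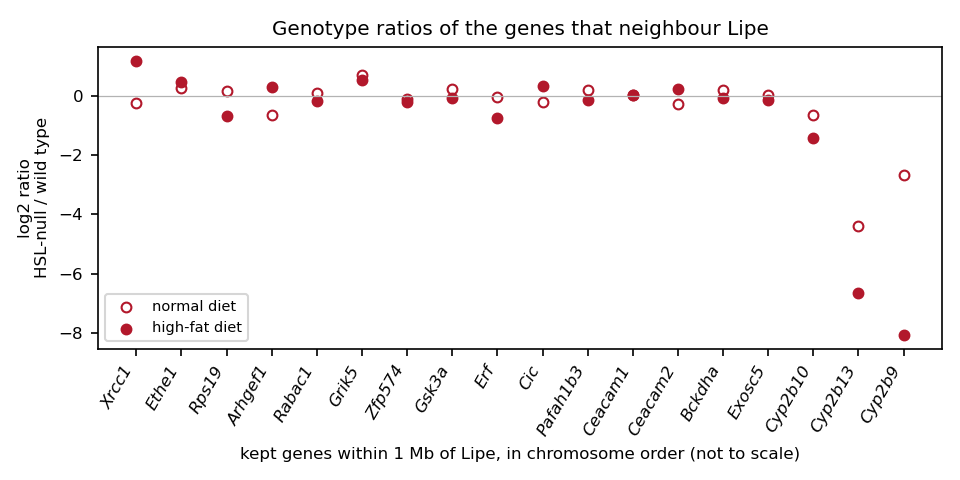
Log2 ratio of HSL-null to wild type (vertical axis) for the 18 kept genes within 1 Mb of Lipe, in chromosome order and not to scale. Open circles are ND and filled circles FD, 1 ratio of 2 arrays each; Cyp2b13 and Cyp2b9, at the right, lie at -4.40 and -2.66 on ND and at -6.64 and -8.06 on FD, with signals at the floor counted as the floor.

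On ND, HSL-null liver had 24 genes 2-fold or more higher and 52 lower than wild type, or 76 of 4829. The lowest was Cyp2b13, at the floor in HSL-null liver, and genes of the exocrine pancreas and Cyp2b9 were among the next. Prss2, which encodes a trypsinogen, was 8.94-fold lower (a log2 ratio of -2.35 with the floor at the median) and Ctrb1, which encodes a chymotrypsinogen, 4.22-fold lower. The pancreas markers had a median log2 ratio of -1.56 over 8 measured genes, below the 10000 random lists, with 6 of them 2-fold or more lower, among them Reg1 (-1.95) and Clps (-1.64). The signals stood out on the wild-type ND array, where Ctrb1 had 286.3 and Clps 118.8, against 49.8 to 74.1 and 38.2 to 43.2 on the other arrays. Tbc1d10a and the vesicle fusion gene Nsf (-2.47, signals 39.9 and 7.2, and -0.58 with the floor at the median) were the other genes of the 5 lowest above the floor. Gpcpd1, Igfbp1, Gtf2f2 (1.81), Immt (1.57, but -0.71 at a probe set under the filter) and Blvra, which encodes biliverdin reductase (1.5), were the 5 highest, with Gpcpd1 at 1.42 and Gtf2f2 at 1.05 with the floor at the median.

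Genes of cholesterol synthesis were higher in HSL-null liver on ND, with a median log2 ratio of 0.37 over 15 measured genes, above the 10000 random lists. Of these, 12 were above 0 and none reached 2-fold. Cyp51 (0.80), Hmgcs1 (0.80), Mvd (0.75) and Msmo1 (0.65), which act at different steps of the pathway, had the largest ratios. The cytosolic heat shock genes were lower, with a median of -0.39 over 14 genes, below the 10000 random lists, and 12 of them below 0. Hspa1b, Hsph1, the chaperone gene Hsp90aa1 (-0.74) and Dnajb1 (-0.57), which encodes a co-chaperone, led the list. The female-biased liver genes had a median of -0.23 over 7 genes (percentile 0.155) whose members went both ways, from Cyp2b13 and Cyp2b9 to the sulfotransferase gene Sult3a1 (1.44) and Hao2, which encodes a hydroxyacid oxidase (0.43).

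Markers of blood and immune cells were lower in HSL-null liver on ND. Kupffer cell and macrophage markers had a median log2 ratio of -0.18 over 20 genes (percentile 0.21), with Itgax (-1.05), Il1b (-1.03), Laptm5 (-0.66) and, higher, the scavenger receptor gene Msr1 (0.61). Lymphocyte and antigen-presenting cell markers had -0.28 over 12 genes (percentile 0.82), with Ptprc, the CD45 gene (-0.97), and Cd79b, part of the B cell receptor (-0.95). Red blood cell markers had -0.36 over 6 genes (percentile 0.35), with 6 of 6 below 0, among them Bpgm (-0.53) and Car2 (-0.50), but -0.29 and inside the range with no filter on low values. Hepatocyte secretory markers had -0.16 over 19 genes (percentile 0.23), with Hnf4a (-0.45), Cebpa (-0.36) and Alb, the albumin gene (-0.36), but 0.0083 under quantile normalization. The macrophage median was -0.083 and the lymphocyte median -0.11, both inside the range, with the mean of a gene's probe sets. On FD against ND, macrophage and lymphocyte medians were -0.50 and -0.48 in wild type, and -0.044 and -0.11 in HSL-null liver. The genotype comparison on ND and the diet comparison in wild type share the wild-type ND array. Part of the lower immune markers could thus be high values on that array. Red blood cell markers had -0.043 for diet in wild type. Median scaling shifted the median of all genes by 0.13 and gave 30 higher and 36 lower genes, quantile normalization gave 28 and 38, and 24 higher and 44 lower genes were left without the marker genes of other cell types.

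On FD, HSL-null liver had lower expression of cholesterol synthesis genes than wild type. The 15 measured genes were all below 0, with a median log2 ratio of -1.19, below the 10000 random lists, and 9 of them were 2-fold or more lower. Mvd, which encodes mevalonate diphosphate decarboxylase, was 4.92-fold lower (signals 58.1 and 11.8, with a log2 ratio of -1.12 with the floor at the median), Idi1, which encodes isopentenyl diphosphate isomerase, had a log2 ratio of -1.84 (366.9 and 102.4), Sqle, which encodes squalene epoxidase, was 3.54-fold lower (258.4 and 72.9), and Fdps, which encodes farnesyl diphosphate synthase, had -1.69 (1211 and 375.2). Hmgcs1 (-0.10) and Mvk (-0.18) had the ratios nearest to 0, though another probe set of Mvk, with a mean signal of 26.8 just under the filter, had -1.95. Mvk was chosen after its values were seen. Under quantile normalization, median scaling and cyclic loess the median lay at -1.31 or lower.

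Fatty acid synthesis genes were also lower in HSL-null liver on FD, with a median of -0.37 over 13 genes (percentile 0.07). Thrsp, a regulator of lipogenesis, had -1.26 and Me1, which encodes malic enzyme, -0.87, while Scd2 had 0.99. Elovl6 had 0.62 at its brightest probe set and -0.28 at another. Among genes on which the list centres, Fasn, which encodes fatty acid synthase, had -0.61, Scd1, the stearoyl-CoA desaturase of liver, -0.37 and Srebf1, the gene of SREBP-1, 0.25. Xenobiotic metabolism genes had a median of -0.26 over 26 genes (percentile 0.01), with the cytochrome P450 genes Cyp2c39 (-2.01, signals 1985 and 494.3) and Cyp2b10 (-1.43) and the glutathione transferase genes Gsta4 (-1.33) and Gstm6 (-1.30). Female-biased liver genes had -0.73 over 7 genes, below the 10000 random lists, with Cyp17a1 (-1.21) and Sult3a1 (-0.73) after the 2 Cyp2b genes. Cytosolic heat shock genes had -0.56 over 14 genes, below the 10000 random lists, with Hspa1a at -1.83 and Chordc1 at -0.64. Oxidative phosphorylation genes had -0.28 over 28 genes (percentile 0.01), with Ndufa2 (-0.75), Ndufb8 (-0.62) and Sdhb (-0.44) lower and Cycs (0.63) higher. On FD against ND, the xenobiotic, female-biased and oxidative phosphorylation medians were 0.26, 0.64 and 0.14 in wild type. In HSL-null liver they were -0.084 (percentile 31.4), 0 (percentile 58.3) and -0.11 (percentile 8.56), inside the range. The female-biased median there was -0.33 (percentile 0.12) with a pseudocount. By medians, the xenobiotic and female-biased differences went more with high values on the wild-type FD array. Low values on the HSL-null FD array entered too. In wild type and HSL-null liver, Cyp2c39 had FD to ND ratios of 0.010 and -1.95, and Cyp17a1 -0.060 and -1.33. Gsta4 went the other way, with 1.68 and -0.12. The female-biased means were 0.90 and -0.82. Of 28 oxidative phosphorylation genes, 19 were above 0 in wild type and 24 below 0 in HSL-null liver. After Cyp2b9 and Cyp2b13, at the floor in HSL-null liver, the 5 lowest single genes were Usp2, Slc48a1, which encodes a heme transporter (-2.53, or -1.74 with the floor at the median), Mvd, Hspa1b and 0610005C13Rik (-2.01).

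Acute phase genes were higher in HSL-null liver on FD, with a median log2 ratio of 0.28 over 26 genes, above the 10000 random lists. Saa2, which encodes a serum amyloid A protein, had 2.18 (signals 785.7 and 3552), Lcn2, which encodes lipocalin 2, had 1.43 (another probe set 0.29), the metallothionein gene Mt2 1.10 and Orm2 1.10. Kupffer cell and macrophage markers had a median of 0.29 over 20 genes (percentile 99.8), with Il1b at 1.47, Mpeg1 at 0.81 and Msr1 at 0.69. On FD against ND the acute phase and macrophage medians were -0.47 and -0.50 in wild type, and -0.079 (percentile 39.8) and -0.044 (percentile 11.5), inside the range, in HSL-null liver, so that these differences on FD went with low values on the wild-type FD array. Stellate cell and extracellular matrix markers had 0.41 over 17 genes (percentile 99.7), with the receptor gene Pdgfra at 1.29, the collagen gene Col3a1 at 0.76 and Acta2 at 0.72, but 0.059 and inside the range under the stricter filter on signal. Plk1, a mitotic kinase gene, was 6.43-fold higher, T2 6.29-fold, Jchain, which encodes the joining chain of antibodies, 6.06-fold and Igh-VS107, an immunoglobulin gene, 5.16-fold, with signals of 8.4 to 15.4 in wild type. With the floor at the median their log2 ratios were 1.46 for Plk1, 0.98 for T2, 1.81 for Jchain and 0.77 for Igh-VS107, and another probe set of Plk1 went the other way, at -0.28. These 4 genes and Igfbp1 were the 5 highest. In all, 90 genes were 2-fold or more higher and 46 lower, or 136. Median scaling shifted the median of all genes by -0.17 and turned the balance to 51 higher and 72 lower, quantile normalization gave 63 and 59, cyclic loess 58 and 58, and without the marker genes of other cell types 85 were higher and 45 lower.

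**Figure D3:**
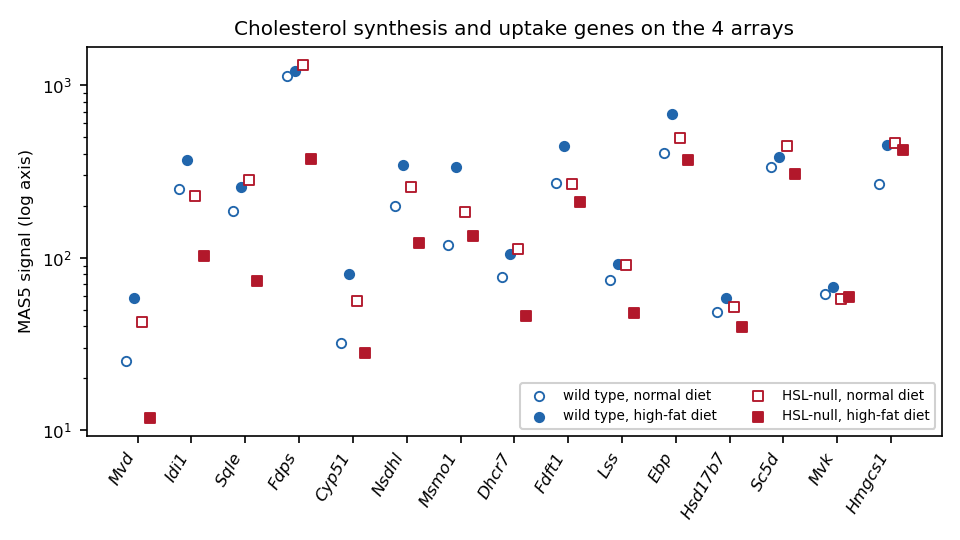
MAS5 signal (log axis) of the 15 measured genes of cholesterol synthesis on the 4 arrays, 1 point per array, ordered by the log2 ratio of HSL-null to wild type on FD. Circles are wild type and squares HSL-null, open on ND and filled on FD; the filled square lies below the filled circle for each of the 15 genes, for Mvd at 11.8 against 58.1.

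In wild-type liver, FD was accompanied by lower signals of Lepr, the leptin receptor gene (20.9-fold lower, signals 156.4 and 7.5), of Elovl6, which encodes a fatty acid elongase (5.62-fold, and 2.74-fold at another probe set), of the chemokine gene Cxcl1 (4.99-fold) and of Itgb2, which encodes a leukocyte integrin (4.79-fold). Sult3a1 was 4.95-fold higher and Cyp2b13 4.73-fold higher than on ND. With Ccdc186 (-2.52, or -0.66 with the floor at the median) these were among the 5 lowest and 5 highest genes above the floor, and Muc1 (2.06, or 0.93 with that floor), Gm7775 (1.84, or 0.90) and Gsta4 (1.68) completed the highest. Prss2, at the floor on FD, was at least 22.3-fold lower. In all, 38 genes were 2-fold or more higher on FD and 114 lower, or 152.

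The cholesterol synthesis genes of wild-type liver were higher on FD, with 15 of 15 above 0 and a median log2 ratio of 0.56, above the 10000 random lists. Msmo1 (1.51), Cyp51 (1.33), Mvd (1.21) and Nsdhl (0.79), of which the first 3 were 2-fold or more higher, led the list. Genes of fatty acid oxidation and PPARA targets had a median of 0.31 over 27 genes, above the 10000 random lists, with 21 above 0. Among them were the acyl-CoA thioesterase gene Acot1 (1.03), Ehhadh (0.88) and Ech1 (0.85), which encode peroxisomal enzymes of oxidation, whereas Fabp1 had -0.80. Ppara had 0.099 and Cpt1a, which encodes the enzyme of fatty acid entry into mitochondria, -0.21. Xenobiotic metabolism genes had 0.26 over 26 genes (percentile 99.99), with Gsta4, Ephx1, which encodes an epoxide hydrolase (1.24), Gsta2 (1.10) and Aldh1a7 (1.01). Female-biased liver genes had 0.64 over 7 genes, above the 10000 random lists, with Sult3a1, Cyp2b13, Hao2 (1.41) and Cyp2b9 (0.64). Retinoid metabolism genes had 0.25 over 11 genes (percentile 99.5), with Retsat (1.12) and Rdh5 (0.75), but 0.14 and inside the range under the stricter filter. Oxidative phosphorylation genes had 0.14 over 28 genes (percentile 98.05), with Ndufb8 (0.75) and Atp5k (0.66), and 0.13 and inside the range with a pseudocount.

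Markers of inflammation and of immune cells were lower on FD in wild-type liver. The acute phase genes had a median of -0.47 over 26 genes, below the 10000 random lists, with Saa2 (-1.64), Mt2 (-1.01), Lcn2 (-0.93) and Stat3 (-0.73). Kupffer cell and macrophage markers had -0.50 over 20 genes, below the 10000 random lists, with Il1b (-1.41) and Itgax (-1.35). Lymphocyte and antigen-presenting cell markers had -0.48 over 12 genes (percentile 0.25), with Ptprc (-1.80), Jchain (-1.65) and Cd52 (-0.90), but -0.14 and inside the range under the stricter filter. Pancreas markers had -1.39 over 8 genes, below the 10000 random lists, and the wild-type ND array held the highest signal of 6 of them, with Ctrl and Cela1 as exceptions. Hepatocyte secretory markers had -0.31 over 19 genes (percentile 0.86), with Cps1 (-0.60) and Alb (-0.47), but -0.013 under quantile normalization. Median scaling shifted the median of all genes by 0.14 and gave 61 higher and 74 lower genes, quantile normalization gave 48 and 84, and without the marker genes of other cell types 38 were higher and 104 lower.

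In HSL-null liver, genes of cholesterol and fatty acid synthesis were lower on FD than on ND. The cholesterol synthesis genes had a median log2 ratio of -0.93 over 15 genes, below the 10000 random lists, with 14 below 0 and 6 of them 2-fold or more lower. Sqle was 3.88-fold lower, Mvd 3.6-fold lower (-0.67 on the log2 scale with the floor at the median), Fdps had -1.81 and Dhcr7, which encodes the last enzyme of the pathway, -1.30. Fatty acid synthesis genes had -0.70 over 13 genes, below the 10000 random lists, with 5 of them 2-fold or more lower. These were Elovl6 (-1.67), Me1 (-1.29), Acly, which encodes ATP citrate lyase (-1.27), Fasn (-1.24) and Pklr, which encodes liver pyruvate kinase (-1.02). Pklr was chosen after its values were seen. Scd1 had -0.67 and Srebf1 0.55. Genes of fatty acid oxidation and PPARA targets had 0.17 over 27 genes, above the 10000 random lists, with Cyp4a14 (0.61), Slc25a20 (0.41) and Vnn1 (0.41) higher and Pdk4 (-0.45) lower.

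Among single genes of HSL-null liver, Lepr was 5.43-fold lower on FD, Slc48a1 4.83-fold lower (-1.49 on the log2 scale with the floor at the median) and Cyp2c39 3.87-fold lower. With Sqle and Mvd these were the 5 lowest above the floor, and Cyp2b9, at the floor on FD, was at least 27.2-fold lower. Nsf was 6.28-fold higher (signals 7.2 and 45.2, and a log2 ratio of 0.76 with the floor at the median), the immediate early gene Fos 3.51-fold, Chrne 3.23-fold (a log2 ratio of 0.64 at a probe set under the filter), T2 3.14-fold and Sema5b 3.09-fold, the last 2 at 0.98 and 0.90 on the log2 scale with the floor at the median. Cell cycle genes had a median of 0.36 over 14 genes (percentile 99.7), with the growth arrest genes Gadd45a (1.16) and Gadd45b (0.97) and Mcm4 (0.87) higher and the cyclin gene Ccne1 (-1.31) lower, but 0.19 and inside the range with no filter on low values. Stellate cell and extracellular matrix markers had 0.27 over 17 genes (percentile 99.7), with Col1a1 (0.95) and Col3a1 (0.70), but -0.076 under the stricter filter on signal. Interferon response and antigen processing genes had -0.14 over 23 genes (percentile 0.29), with Cxcl9 at -0.99. Clock genes had -0.15 over 14 genes (percentile 0.29), with Per1 (-1.82) and Tef (-0.81), and -0.063 and inside the range with the floor at the median. Lymphocyte and antigen-presenting cell markers had a median of -0.11 over 12 genes (percentile 2.17) and a mean of 0.059, since Ighm (1.12, but 0.033 and 0.68 at other probe sets) and Jchain (1.0) were higher and Cd74 (-0.64) lower. Their median was 0.014 with no filter on low values. In all, 40 genes were 2-fold or more higher and 30 lower, or 70. Median scaling shifted the median of all genes by -0.16 and turned the balance to 22 higher and 48 lower, quantile normalization gave 28 and 39, cyclic loess 27 and 39, and without the marker genes of other cell types 38 were higher and 29 lower.

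Lepr, Elovl6 and Fabp5, a fatty acid binding protein gene, were lower on FD in both genotypes. Their mean log2 ratios of FD to ND were -3.41 ± 1.37 for Lepr, -2.08 ± 0.58 for Elovl6 and -1.68 ± 0.038 for Fabp5 (SD, n = 2 array pairs). The Lepr signals on FD were near the floor, and with the floor at the median the ratios were -2.55 and -1.79. Per1 (mean -1.35, with a ratio of 0 in HSL-null liver with that floor), the polymerase subunit gene Pold2 (-1.25), Snhg6 (-1.05), Ulk1, an autophagy kinase gene (-1.04), Pdzk1ip1 (-0.95), Zbtb16 (-0.83) and the elongase gene Elovl1 (-0.74) followed. The higher genes had smaller ratios, led by Pik3r2 (1.18), which encodes a regulatory subunit of PI3-kinase, Ctse, which encodes cathepsin E (1.14), and the transporter gene Abcg2 (0.94). The probe set of Ctse without a suffix had 1.15 in wild type and went the other way in HSL-null liver, at -3.00. Csad, which encodes an enzyme of taurine synthesis, had a mean of 0.84, Grik5 0.83, the phosphate transporter gene Slc20a1 0.80, Cse1l 0.79, Cks1b 0.78, Brip1os 0.77 and Map3k11 0.69. With the floor at the median, Grik5 had 0.13 in wild type, and Brip1os 0.47 and Map3k11 0.33 in HSL-null liver. In all, 0 genes were 2-fold or more higher in both genotypes, where independent lists would share 0.315 and matched draws 0.395, with at most 3. The 4 lower genes were Elovl6, Fabp5, Lepr and Prss2, where independent lists would share 0.708 and matched draws 0.712, with at most 4, and 3 were left without the marker genes of other cell types. The 2 diet ratios had a Pearson correlation of -0.026 and a Spearman correlation of -0.048 across the 4829 genes.

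Among genes above the floor, the genotype ratio differed most between diets for Cxcl1 and, in the other direction, for Mvd, Slc48a1 and Sqle. Cxcl1 had a log2 ratio of HSL-null to wild type of -1.80 on ND and 1.98 on FD, a difference of 3.78, and its other probe set gave -1.60 and 2.20. T2 (3.65), Igh-VS107 (3.37), Plk1 (3.13) and Ccdc186 (2.73) were the other genes above the floor with the highest differences, which were 1.31, 1.248, 1.91 and 0.88 with the floor at the median. The difference of Plk1 rested on 1 probe set, as another had log2 ratios of -0.25 on ND and -0.28 on FD. The lowest above the floor were Mvd (-3.05), Slc48a1 (-2.70), Sqle (-2.43), Cyp51 (-2.32) and Muc1 (-2.20), of which Mvd had -1.79, Slc48a1 -1.92 and Muc1 -1.04 with the floor at the median. In all, the difference was 2-fold or more for 305 genes, 238 higher and 67 lower on FD. Median scaling turned the balance to 114 higher and 211 lower, quantile normalization gave 149 and 117, cyclic loess 155 and 112, and without the marker genes of other cell types 219 were higher and 67 lower. A further 10 genes, named after their values were seen, were 2-fold or more lower on FD in wild type and 2-fold or more higher on FD in HSL-null liver, against 0.944 for independent lists and 1.65 for matched draws, with at most 7: Cxcl1, Egr1, Igh-VS107, Igkv6-23, Il1b, Krtap3-1, Pip4k2a, Plk1, Ptpn22 and T2. Mvd alone went the opposite way.

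**Figure D4:**
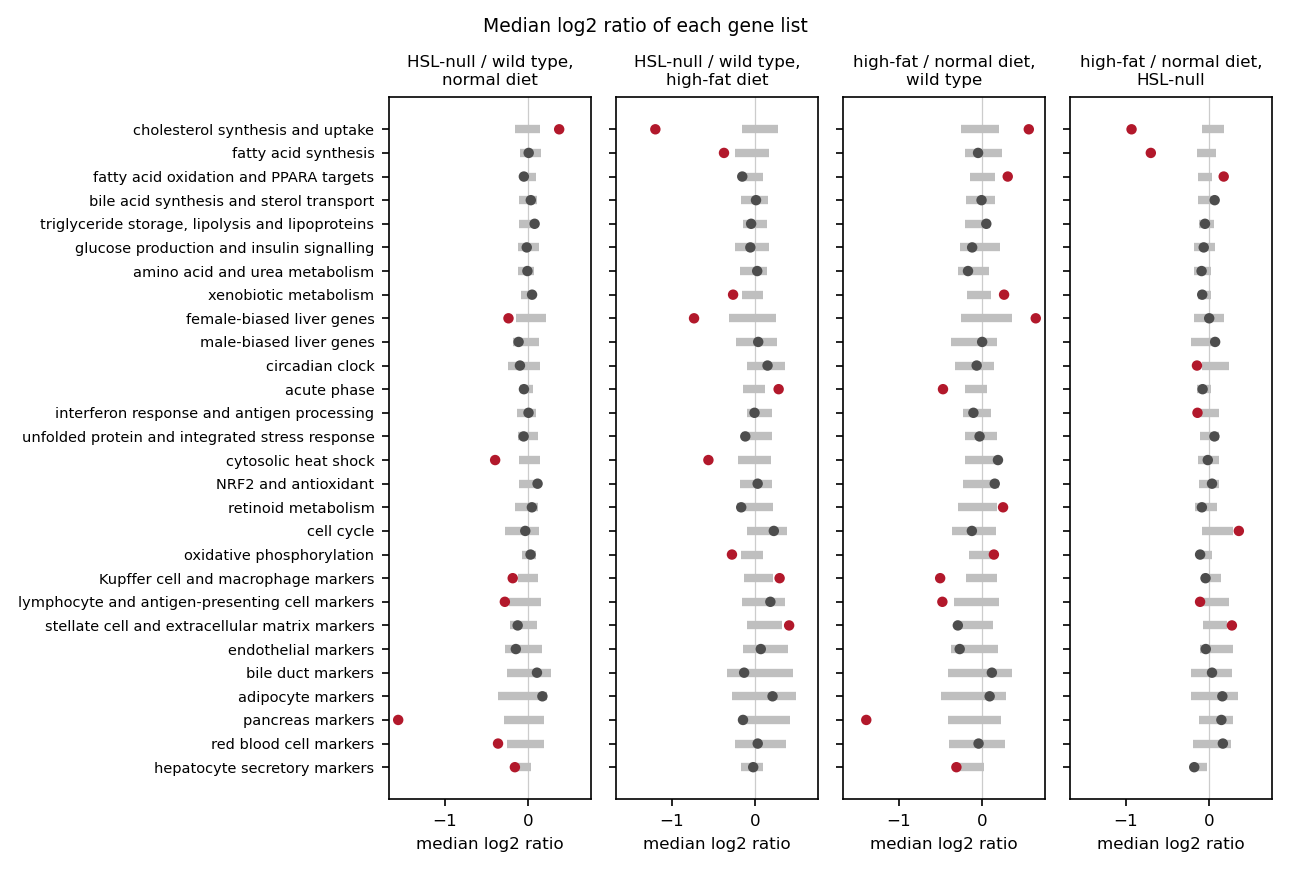
Median log2 ratio (horizontal axis) of the 28 gene lists in the 4 comparisons, 1 point per list. Grey bars span the central 95% of 10000 random lists matched on size and mean signal, and red points lie outside; the cholesterol synthesis list lies at 0.37, -1.19, 0.56 and -0.93 from the left panel to the right, and the hepatocyte secretory list in the left panel changes sign under quantile normalization.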

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

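The tests of explanations given here for the cholesterol synthesis genes were chosen after the result was seen.

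Genes of cholesterol synthesis had opposite genotype ratios on the 2 diets, with a median log2 ratio of HSL-null to wild type of 0.37 on ND and -1.19 on FD, a difference of -1.57, and opposite diet ratios in the 2 genotypes, 0.56 in wild type and -0.93 in HSL-null liver, a difference of -1.49. For each gene these 2 differences are the same number by construction, so they describe 1 pattern. They were not tested, since each group was 1 array. Scaling between arrays was argued against by the other scalings, whose median nearest to 0 on FD was -1.31, and an odd wild-type FD array as the whole cause by HSL-null liver on FD against ND, which does not use that array and gave -0.93. A smaller share of hepatocyte RNA was argued against by the hepatocyte secretory markers, whose median on FD was -0.022, with 0 of 19 as low as -0.60. Both low medians, -1.19 and -0.93, use the same HSL-null FD array, and both high medians, 0.37 and 0.56, the same wild-type ND array. An odd HSL-null FD or wild-type ND array thus remains open. An effect of genotype on the response to FD and the smaller pool of 4 livers, in which 1 unusual animal could weigh more, also remain open and were not tested.

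Kupffer cell and macrophage markers were lower in HSL-null liver on ND and higher on FD, with medians of -0.18 and 0.29, a difference of 0.48 that was not tested. The ND median was -0.083, inside the range, with the mean of a gene's probe sets. On FD against ND the median was -0.50 in wild type and -0.044 in HSL-null liver, so the FD side went with low values on the wild-type FD array. Several single genes also had opposite directions, and none of these differences was tested. Between the 2 genotype ratios the difference was 2.36 for Chrne, 3.78 for Cxcl1, 3.37 for Igh-VS107 and 2.38 for Itgb2. Between the 2 diet ratios it was 3.78 for Cxcl1, 3.37 for Igh-VS107, -3.05 for Mvd, 3.13 for Plk1 and 3.65 for T2. With the floor at the median, the difference was 1.248 for Igh-VS107, -1.79 for Mvd, 1.91 for Plk1 and 1.31 for T2. Another probe set of Plk1 had diet ratios of -0.16 and -0.19, and a probe set of Chrne under the filter had genotype ratios of -1.53 on ND and -1.05 on FD, so the opposite directions of Plk1 and Chrne each rest on 1 probe set. For Cxcl1 and Igh-VS107 both differences are the same number by construction.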

How the results depend on the processing

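The alternative without marker genes of other cell types was chosen after seeing the data, and it left every count within 1.5 times. Median scaling, quantile normalization and cyclic loess also left the 7 counts within 1.5 times, though not their split into higher and lower. Of the 36 list medians outside the range, 23 had the same call under every alternative run, among them the cholesterol synthesis list in 4 comparisons and the heat shock list in 2. Of 76 inside, 63 had the same call, and 17 values moved outside under 1 or another alternative, among them the clock list on ND, to -0.29 without suffix probe sets, and lymphocyte markers on FD, to -0.34 under the stricter filter. Of 121 ratios of named genes, 72 moved by less than the probe error of 0.298 throughout, 88 values moved by more and 1 changed sign. Without a filter, low signals near the floor entered, and higher thresholds or a stricter filter admit fewer genes by construction. For the other values the cause was not tested.

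For genotype on ND the 76 genes became 47 with the floor at the median, 45 with a pseudocount, 313 without a filter, 14 under the stricter signal filter, 325 at 1.5-fold and 18 at 3-fold. For genotype on FD the 136 became 89 with the floor at the median, 419 without a filter, 44 under the stricter filter, 625 at 1.5-fold and 35 at 3-fold. For diet in wild type the 152 became 480 without a filter, 47 under the stricter filter, 678 at 1.5-fold and 39 at 3-fold. For diet in HSL-null liver the 70 became 46 with the floor at the median, 290 without a filter, 30 under the stricter filter, 311 at 1.5-fold and 16 at 3-fold. For the difference in genotype ratio the 305 became 884 without a filter, 86 under the stricter filter, 1092 at 1.5-fold and 91 at 3-fold. The 9 genes of both diets became 26, 5, 43 and 5 in that order, and the 4 of both genotypes became 29 without a filter, 2 under the stricter filter and 43 at 1.5-fold. Under the stricter filter the correlation of the genotype ratios was 0.13, the probe error 0.212 and the share near Lipe 40.0%. The probe error was 0.265 with the floor at the median, and the share near Lipe was 33.3% with a pseudocount.

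With the floor at the median, these medians moved inside the range: clock genes in HSL-null diet to -0.063, lymphocyte markers in HSL-null diet to -0.084 and stellate markers on FD to 0.30. With a pseudocount oxidative phosphorylation in wild-type diet moved to 0.13. Without a filter retinoid genes in wild-type diet moved to 0.017, cell cycle genes in HSL-null diet to 0.19, lymphocyte markers on ND to -0.18 and in wild-type diet to -0.15, stellate markers on FD to 0.059 and in HSL-null diet to 0.17, and red cell markers on ND to -0.29, while lymphocyte markers in HSL-null diet changed sign, to 0.014. Under the stricter filter retinoid genes moved to 0.14, oxidative phosphorylation in wild-type diet to 0.12, lymphocyte markers on ND to -0.092 and in wild-type diet to -0.14 and stellate markers on FD to 0.059, while stellate markers in HSL-null diet changed sign, to -0.076. With the mean of a gene's probe sets clock genes in HSL-null diet moved to -0.067, oxidative phosphorylation in wild-type diet to 0.12, macrophage markers on ND to -0.083 and lymphocyte markers on ND to -0.11. Without suffix probe sets clock genes moved to -0.047, oxidative phosphorylation in wild-type diet to 0.14, lymphocyte markers on ND to -0.11, and Ctse in HSL-null diet changed sign, to -3.00. Under quantile normalization hepatocyte markers moved to -0.013 in wild-type diet and changed sign on ND, to 0.0083.

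On each array 24.1 to 26.0% of the probe sets lay at or under the floor. The floor is itself a percentile of these values over all arrays, so such a share arises by construction. It does not measure detection, and how well low signals were detected was not tested.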

Other observations

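The tests of explanations for the Cyp2b and clock genes were chosen after the results were seen, except that the share of genes near Lipe was a planned comparison, and Arntl, Nfil3, Tef, Nr1d1, Per3 and Cry2 were chosen as examples after their values were seen.

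Several gene groups had medians inside the range of random lists in all 4 comparisons. In the order genotype on ND, genotype on FD, diet in wild type and diet in HSL-null liver, bile acid synthesis and sterol transport genes had medians of 0.034, 0.011, -0.0070 and 0.065 over 19 genes, although Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 0.66 for diet in wild type and 1.21 in HSL-null liver, with signals of 111.1 and 175.1 and of 92.6 and 213.6. Genes of triglyceride storage, lipolysis and lipoproteins had 0.079, -0.047, 0.050 and -0.050 over 24 genes, and Plin2, which coats lipid droplets, had 0.0092, 0.14, -0.17 and -0.039. Glucose production and insulin signalling genes had -0.015, -0.056, -0.12 and -0.065 over 11 genes apart from the high ratios of Igfbp1, with Pck1 at 0.25, 0.40, -0.43 and -0.27 and G6pc at 0.068, 0.84, -0.84 and -0.065. Amino acid and urea genes had -0.0068, 0.026, -0.17 and -0.091 over 15 genes, the unfolded protein and integrated stress response -0.052, -0.12, -0.031 and 0.062 over 19, NRF2 and antioxidant genes 0.11, 0.031, 0.15 and 0.034 over 15, and male-biased liver genes -0.11, 0.038, 0.00032 and 0.071 over 7. Some of these moved outside under 1 or another alternative, among them the male-biased genes in HSL-null diet, at 0.22 under quantile normalization, and in wild-type diet, at 0.39 without a filter, and the unfolded protein genes in wild-type diet, at -0.22 under the stricter filter.

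Of cell types, endothelial markers had -0.15, 0.069, -0.27 and -0.041 over 10 genes, bile duct markers 0.11, -0.13, 0.12 and 0.034 over 5, and adipocyte markers 0.17, 0.21, 0.090 and 0.16 over 5, while Adipoq, with signals of 18.1, 9.2, 4.8 and 4.9, lay under the filter. In total 36 of 112 list medians lay outside the central 95% of random lists, where 5% would by construction if the genes of a list moved independently.

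Cyp2b9 and Cyp2b13 were lower in HSL-null liver on both diets, and both lie close to Lipe. The 22.2% of genes different on both diets that lay within 10 Mb of Lipe, against 1.99% of kept genes, are these same 2 genes, so the share restates the observation and a change of the genome next to the targeted gene remains open. A block of foreign genome that alters most genes around Lipe was argued against, since the other 94 kept genes within 10 Mb had a median size of the mean genotype ratio only 1.11 times that elsewhere. A loss of female-type expression as a whole was argued against on ND, where the median of the other 5 measured female-biased genes was 0.054, but on FD it was -0.61 with all 5 below 0, so that a loss on FD alone remains open. A sequence difference under the probes and an effect of HSL loss on these genes were not tested.

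Of the clock genes, Usp2, Dbp, Per1 and Tef were lower and Arntl and Nfil3 higher in HSL-null liver on both diets, with Arntl at 0.51 and 1.65, Nfil3 at 1.26 and 0.54 and Tef, an output gene, at -0.63 and -1.57, although a second probe set of Nfil3 had -0.68 on ND and Nr1d1, Per3 and Cry2 had ratios from -0.060 to 0.26. Livers taken at another phase of the daily cycle could give such opposite arms. Over all genes of both arms the output median minus the Arntl-side median was -1.12 on ND and -0.88 on FD, below the range of random lists, but this included the genes that drew attention. After that was seen, the test was repeated without them, and the difference was -0.20 on ND and -0.49 on FD, inside the range, with 7 genes, so that phase remains undecided. The 2 solution lots, 1 per genotype, and the genotype cannot be told apart.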
